A study of Mus musculus with 2 samples.

How the data were processed

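RNA sequencing was used to measure gene expression in mouse acute myeloid leukaemia cells carrying both Mac1 and KIT on their surface, which the labels call leukaemia-initiating cells. They were sorted from bone marrow of C57BL/6 mice whose labels give an age of 8 weeks. There were 2 libraries, 1 labelled wild type (WT) and 1 labelled P2X1 knockout (P2X1-KO). The titles and genotype fields speak of a knockout, whereas the protocol text adds names for a scrambled control and a knockdown, and no choice between these was made here. Whether each library came from 1 animal or from several pooled animals is not given in the sources used here.

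The authors deposited whole-number read counts per gene symbol, not normalized, with 1 column for each library. Reads were aligned with HISAT2 2.0.4 and the genome build was mm10, per the submitters' processing notes. The counting tool, gene annotation, strand setting and read filters are not given in the sources used here. Reads from overlapping genes on opposite strands therefore cannot be assigned with certainty, and near-identical gene copies may have exchanged reads. The table held 46095 genes or gene models, of which 20541 had at least 1 count. Of the table's entries, 27 carried calendar dates in place of symbols, as happens when a spreadsheet converts gene names. They took 0.147% of the counts in the WT library (exact 95% interval 0.145 to 0.149) and 0.110% in the P2X1-KO library (0.108 to 0.113). They stayed in the totals and were not named. The 13 mitochondrially encoded protein genes appeared without the usual prefix, and they were matched to the mitochondrial list after the table had been seen.

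Library totals were 14658620 counts for WT and 9447894 for P2X1-KO. Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, which gave effective library sizes of 15591519 for WT and 8882591 for P2X1-KO. CPM values, the counts scaled to a common library size, were computed from these sizes. The log2 difference of a gene is log2(CPM + 0.5) in the P2X1-KO library minus the same in the WT library, so the pseudocount of 0.5 CPM understates differences of low genes. Folds were computed as ratios of CPM without a pseudocount. Each fold has an exact 95% interval from the binomial distribution of the counts given their sum (Clopper-Pearson), and a count has an exact Poisson interval. Intervals and floors cover counting error only, since reads that share a PCR origin are not independent molecules and no replicate was measured. A count of 0 was set against a floor of 3 counts in that library, equal to 0.192 CPM in WT and 0.338 CPM in P2X1-KO. Such folds are printed as "at least" that value. They leave out the error of the count in the other library, so the lower bound of the exact interval is smaller. The WT library, being deeper, has the narrower intervals for a given CPM.

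With 1 library per group no p-value was computed. The design fixed a count of genes at least 2-fold apart among genes with a mean of at least 5 CPM over both libraries, and the number of these whose whole interval lay beyond 2-fold. It also fixed 40 gene lists. Each list with at least 3 members at a mean of at least 1 CPM was given its median log2 difference. That median was placed among the medians of 10000 random lists of the same size, drawn from 50 bins of mean expression. A percentile below 2.5 or above 97.5 is called outside the central 95%. It describes these libraries and not the conditions. Of the 40 lists, 38 had enough members.

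Named genes followed a fixed rule. It took P2rx1, Pbx3, Bcat1, Kit and Itgam in every case. It then took the 12 genes higher and the 12 lower in the P2X1-KO library by the bound of the interval nearest to no change, at a mean of at least 5 CPM, leaving out predicted genes, pseudogenes, unnamed models and replication histones. From each list it took up to 2 members in each direction by the same bound, and from each library the 5 most abundant genes. The lists, this rule and the alternatives not marked otherwise were set before the data were examined. Pbx3 and Bcat1 entered the rule because they were remembered as genes of interest to the study. The same memory was the reason for the HOXA, MEIS1 and PBX3 list and for the branched-chain amino acid list. Those lists were therefore not chosen blind to the study. For lists with too few members for a median, the measured members are named with their counts. Some genes that the rule names are not reported here. Genes named otherwise are marked as chosen after their values were seen.

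Coordinates, exon lengths and GC content came from GENCODE release M21, which is built on the same assembly. Of the genes with at least 1 count, 17745 (86.4%) were matched to it, 359 of them through an older symbol. Exon length and GC content were known for 10226 of the genes with a mean of at least 5 CPM, which is 97.5%. A correction subtracted the median log2 difference within 20 bins of exon length and then within 20 bins of GC content. Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile scaling, total counts without the 20 most abundant genes, pseudocounts of 0.1 and 2 CPM, other filters and fold thresholds, random lists matched otherwise, and the WT library thinned to the total of the other. The length and GC correction and a TMM factor without mitochondrial and rRNA genes were chosen after seeing the data.

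The computation was tested on simulated data for this comparison, with counts drawn from the mean of both libraries and counting noise only, over 10483 genes. All 50 genes planted at 4-fold higher and all 50 at 8-fold higher came out at 2-fold or more (100%), as did the 50 planted at each of the same sizes lower. Of 10283 unchanged genes, 0 reached 2-fold. The intervals held the true ratio for 95.4% of genes. Of 40 random lists 1 fell outside the central 95%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.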

Results

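Gene expression was compared between leukaemia-initiating cells of mice with acute myeloid leukaemia labelled wild type (WT) and cells labelled P2X1 knockout (P2X1-KO). P2X1, encoded by P2rx1, is an ATP-gated cation channel of the plasma membrane. The comparison asks which transcripts differ in these cells when the receptor is lost. The cells were sorted for Mac1, the integrin encoded by Itgam, and for the stem cell factor receptor KIT. There was 1 library per group, so no difference below has a replicate check. The WT library held 14658620 counts over 19824 genes and the P2X1-KO library 9447894 counts over 16165 genes.

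P2rx1 itself was low in both libraries and was not lower in the library labelled P2X1-KO. It lies on chromosome 11 from 72999103 to 73015200 on the plus strand (mm10). P2rx1 had 27 counts in the library labelled WT (95% interval 17.8 to 39.3), or 1.73 CPM, and 45 counts in the library labelled P2X1-KO (32.8 to 60.2), or 5.07 CPM. This was 2.93-fold higher in the library labelled P2X1-KO, with a 95% interval of 1.78 to 4.90. The targeted transcript thus goes against the label, and every direction given below is a difference between the library labelled P2X1-KO and the library labelled WT. Counts per gene do not show which exons were read, so a transcript that lacks a deleted part cannot be recognised from them. The labels name the sample a knockout in some fields and use knockdown wording in another.

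The genes marking the sort were present in both libraries. Kit had 13.3 CPM in the library labelled WT and 19.9 CPM in the library labelled P2X1-KO, a 1.5-fold difference (1.22 to 1.84). Itgam had 307 and 504 CPM, a 1.65-fold difference (1.58 to 1.71). Pbx3, a homeobox gene that acts with HOXA proteins and MEIS1, was 12.7-fold lower in the library labelled P2X1-KO (10.2 to 16.1), at 118 CPM against 9.23 CPM. Pbx3 lies on chromosome 2 from 34171457 to 34373142 on the minus strand. Bcat1, encoding the cytosolic aminotransferase of branched-chain amino acids, had 26 counts in the library labelled WT and 0 in the library labelled P2X1-KO, at least 4.94-fold lower against the floor of 3 counts, with 3.74 as the lower bound of the exact 95% interval. Its mean was under 1 CPM, which is below the level used for lists.

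The medians of the neutrophil and monocyte lists were higher in the library labelled P2X1-KO, and those of the lists for the HOXA programme, MYC and ribosome biogenesis, and cholesterol synthesis were lower. Of 10483 genes with a mean of at least 5 CPM, 1238 (11.8%) were at least 2-fold higher in the library labelled P2X1-KO and 1053 (10.04%) at least 2-fold lower, while 8192 (78.1%) lay within 2-fold. The whole interval lay beyond 2-fold for 982 higher and 651 lower genes. At least 10-fold differences were found for 152 higher and 73 lower genes. Predicted genes, pseudogenes and unnamed models made up 238 of the higher and 105 of the lower genes, and replication histones 12 and 0. Pearson's r of log2 CPM between the libraries was 0.816 across genes, which are not independent replicates. The balance of directions depended on scaling. Of the genes at least 2-fold apart, 54.0% were higher and 46.0% lower with TMM, but 38.9% were higher and 61.1% lower with total counts, and 37.2% and 62.8% after the 20 most abundant genes were also left out of the totals. Upper-quartile scaling moved the balance the other way, to 60.9% higher and 39.1% lower.

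**Figure D1:**
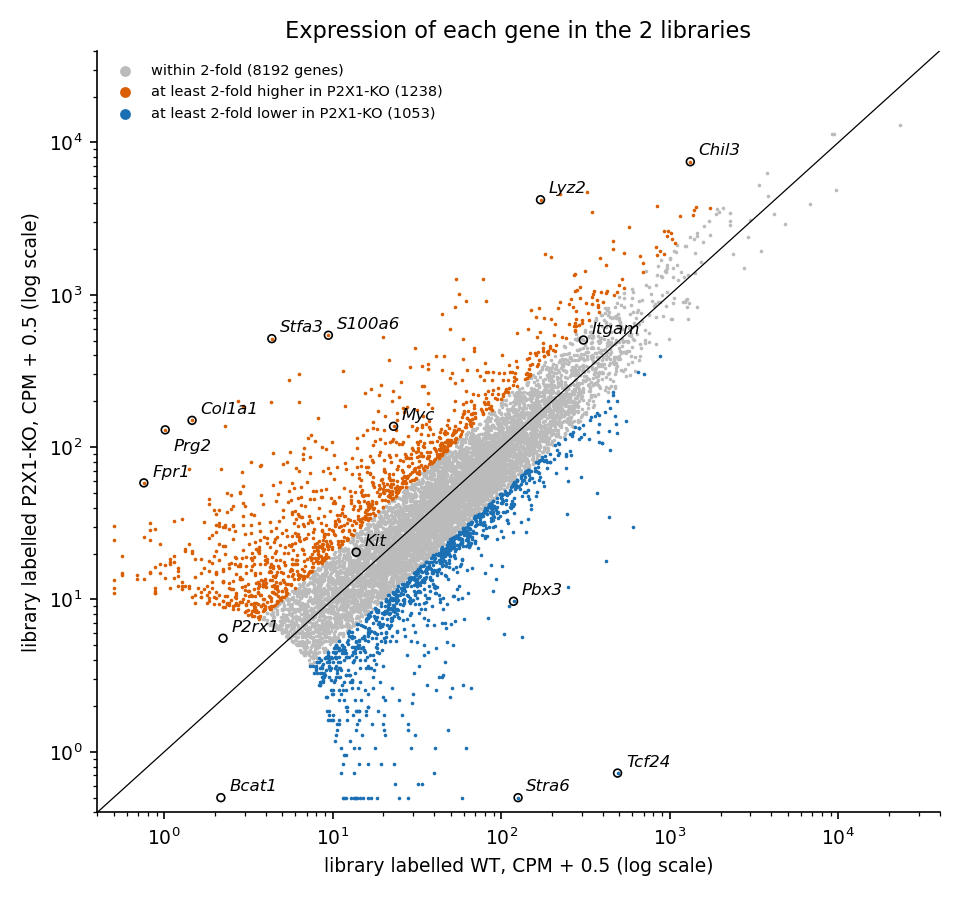
Expression of each gene with a mean of at least 5 CPM in the library labelled WT (x axis) and the library labelled P2X1-KO (y axis), both as CPM + 0.5 on log scales, with 1 library per group and circles around labelled genes, of which P2rx1 and Bcat1 lie under that mean. The 1238 genes at least 2-fold higher are orange, the 1053 at least 2-fold lower blue, and P2rx1 lies above the line of equality at 1.73 and 5.07 CPM.

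The highest genes by the rule included genes of eosinophils and mast cells, fibrillar collagens, and genes of myeloid cells. Prg2, encoding eosinophil major basic protein, was 252-fold higher in the library labelled P2X1-KO (128 to 585), with 8 counts in the library labelled WT and 1149 in the other. Cpa3, a mast cell carboxypeptidase, had 1 and 166 counts, a ratio of 291 (51.6 to 11577). Col1a1 was 155-fold higher (93.8 to 278). Col3a1 and Col1a2 had 0 counts in the library labelled WT and were at least 154-fold and at least 125-fold higher. Fpr1, the formyl peptide receptor of phagocytes, was 225-fold higher (87.4 to 829). The calcium-binding protein genes S100a4 and S100a6 were 75.9-fold and 60.8-fold higher, and the transporter gene Abca9 was 79.1-fold higher. Angptl2, encoding a secreted protein related to angiopoietins, had 0 counts in the library labelled WT and was at least 59.7-fold higher. Stfa3, a stefin of the cysteine protease inhibitor family, was 134-fold higher (104 to 176). Stefin genes are near-identical copies, so its value is uncertain, as is that of Angptl2, which lies opposite to Ralgps1.

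Among the lowest genes by the rule, Tcf24, a basic helix-loop-helix transcription factor gene, had 7628 counts in the library labelled WT and 2 in the library labelled P2X1-KO, a ratio of 2173 (601 to 17945). Stra6, the cellular receptor for retinol-binding protein, had 1953 and 0 counts and was at least 371-fold lower. The counts of Chrnd, an acetylcholine receptor subunit gene, and of Slc15a2, a peptide transporter gene, were also 0 in the library labelled P2X1-KO. They were at least 81.3-fold and at least 72.0-fold lower. Sorcs2, Ppp1r14c, Mlph and C2cd4a likewise had 0 counts there and were at least 52.4-fold, 48.6-fold, 46.3-fold and 43.5-fold lower. Serpinf1, encoding pigment epithelium-derived factor, was 109-fold lower (46.8 to 338). Cttn, encoding the actin-binding protein cortactin, had 518 and 1 counts, a ratio of 295 (52.7 to 11678). Gprasp2 had 612 and 2 counts, a ratio of 174 (48.1 to 1443), and overlaps Bhlhb9 on the same strand, so their reads may not be separable. Stra6 overlaps Ccdc33 on the opposite strand.

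Most measured genes of maturing neutrophils and of monocytes stood higher in the library labelled P2X1-KO. Of 25 measured late neutrophil granule and receptor genes, 19 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 difference of 2.13 (percentile 100 of the random lists). Besides Fpr1, Stfa2l1 was 14.9-fold higher (13.9 to 16.0), subject to the reservation on stefins, and Chil3, a chitinase-like protein gene, was 5.65-fold higher (5.56 to 5.74). In the other direction, G0s2, a lipolysis inhibitor gene that overlaps Lamb3, was 5.0-fold lower, and Ly6g, the neutrophil surface marker gene, was 1.72-fold lower (1.17 to 2.59). Of 21 monocyte and macrophage genes, 18 were at least 2-fold higher and 1 at least 2-fold lower (median 2.22, percentile 100). C1qb, a complement component gene, was 97.6-fold higher (41.3 to 303). Lyz2, encoding lysozyme, had 170 CPM in the library labelled WT and 4207 CPM in the library labelled P2X1-KO. Vcam1 was 3.22-fold lower (2.79 to 3.72), and Ly6c2, at 546 and 497 CPM, was within 2-fold.

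The list of primary granule genes, of the promyelocyte stage, also had a higher median. Of 14 measured, 7 were at least 2-fold higher and 0 at least 2-fold lower (median 0.98, percentile 99.85). Cst7, encoding cystatin F, was 14.6-fold higher (11.8 to 18.3) and Ctsc, encoding the protease that activates granule serine proteases, was 11.2-fold higher (9.33 to 13.5). Mpo, encoding myeloperoxidase, was 1.88-fold lower (1.77 to 2.0), and Nkg7 had 15.3 and 12.7 CPM.

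**Figure D2:**
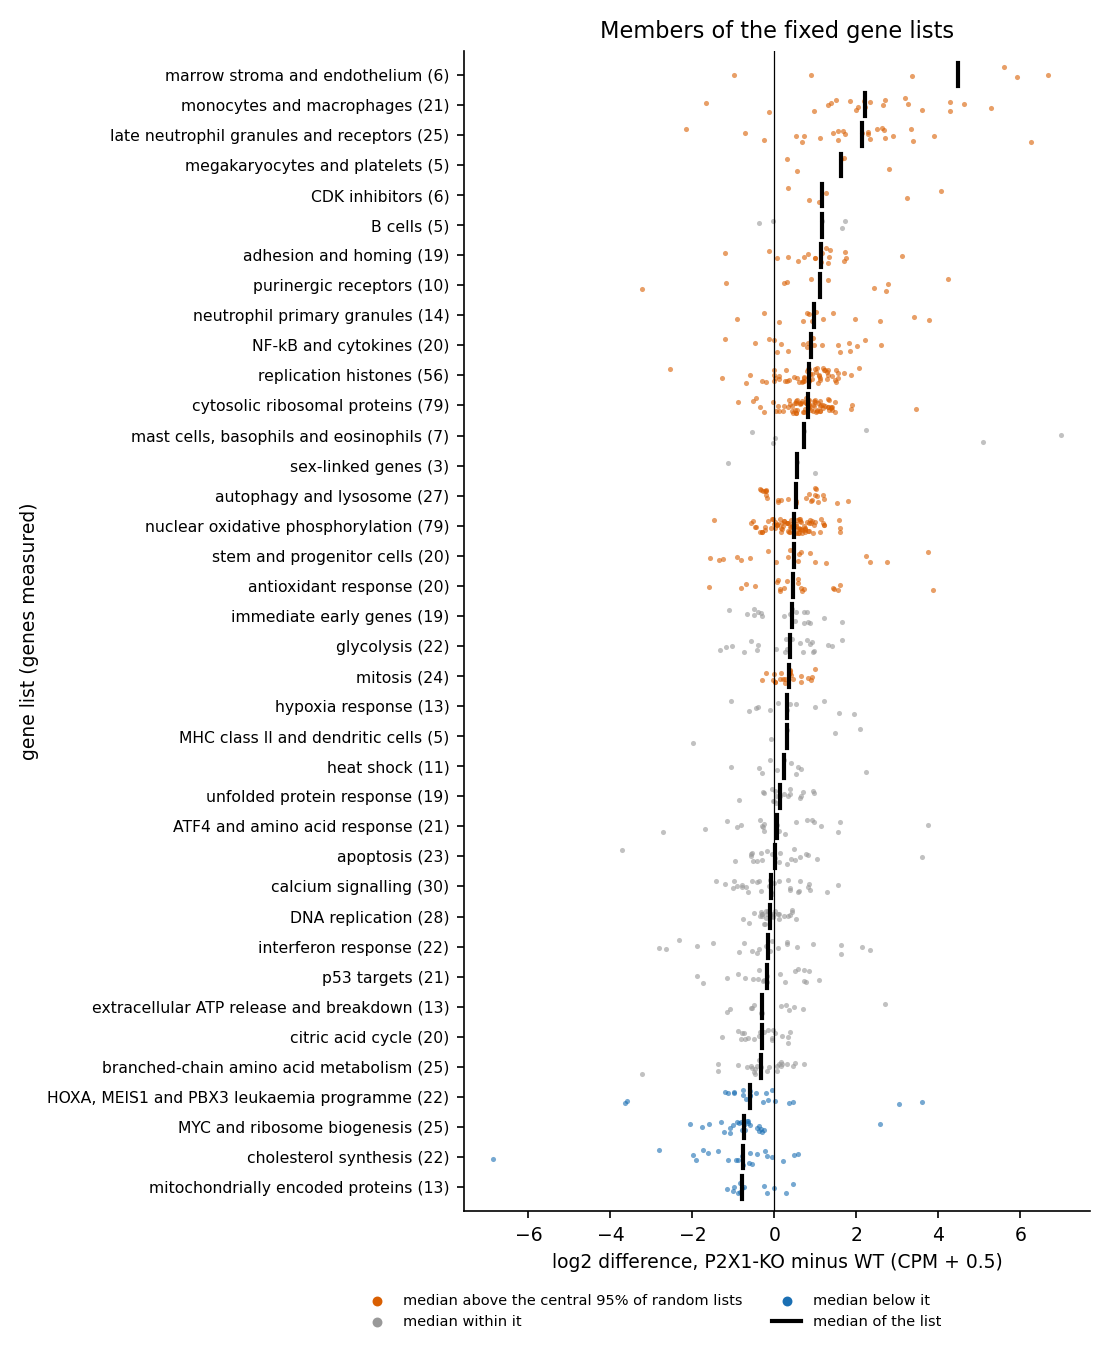
Log2 differences (x axis, P2X1-KO minus WT, CPM + 0.5) of the members of the 38 fixed lists compared with random lists (y axis, number of measured genes in parentheses), 1 library per group. Points are genes (orange, blue or grey where the list median lies above, below or inside the central 95% of random lists) and black bars list medians; the stroma median of 4.48 lies highest, the monocyte and late neutrophil medians of 2.22 and 2.13 follow, and the mitochondrially encoded genes, at -0.78, lie lowest.

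The HOXA, MEIS1 and PBX3 leukaemia list had a lower median in the library labelled P2X1-KO, with members in both directions. Of 22 measured genes, 16 lay within 2-fold, 4 were at least 2-fold lower and 2 at least 2-fold higher (median -0.59, percentile 0.04). Hoxa9 and Hoxa10, named after their values were seen, were nearly level. Pbx3 was among those lower. Bcl2, the apoptosis inhibitor gene, was 14.3-fold higher (10.2 to 20.6) and Mef2c, a transcription factor gene, 8.41-fold higher (7.31 to 9.71). Of 20 stem and progenitor genes, 6 were at least 2-fold higher and 3 at least 2-fold lower (median 0.47, percentile 99.24). Erg was 16.9-fold higher (11.4 to 26.0) and Cd93 6.97-fold higher (5.90 to 8.27), whereas Msi2 was 3.09-fold lower (2.37 to 4.10) and Bmi1 2.62-fold lower (2.16 to 3.19).

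The list of MYC and ribosome biogenesis, which also holds Myc itself and growth genes such as Odc1, had a lower median in the library labelled P2X1-KO. Of 25 measured, 16 lay within 2-fold, 8 were at least 2-fold lower and 1 at least 2-fold higher (median -0.74, percentile 0). Dkc1, encoding the pseudouridine synthase dyskerin, was 4.16-fold lower (3.80 to 4.57) and Odc1, encoding ornithine decarboxylase, 3.40-fold lower (3.19 to 3.63). Myc was the 1 member at least 2-fold higher, at 6.08-fold (5.40 to 6.87). Cytosolic ribosomal protein genes went the other way, with 27 of 79 at least 2-fold higher and 0 at least 2-fold lower (median 0.83, percentile 100, or 0.52 and 99.88 after the length and GC correction). Rpl37a was 3.75-fold higher (3.64 to 3.87), and Rpl3l, a paralog known from muscle, was 19.7-fold higher (9.97 to 44.3). Rpl27 and Rpl10a were 1.86-fold and 1.38-fold lower. These genes took 5.71% of the counts in the library labelled WT (exact 95% interval 5.70 to 5.72) and 8.84% in the other (8.82 to 8.85).

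The medians of cholesterol synthesis genes and of mitochondrially encoded genes were lower. Of 22 cholesterol genes, 8 were at least 2-fold lower and 0 at least 2-fold higher (median -0.78, percentile 0.03). Hsd17b7, an enzyme gene of the pathway, was 9.94-fold lower (5.10 to 22.1), while Fdps was 1.5-fold and Fdft1 1.41-fold higher, the latter opposite to Ctsb. Of 13 mitochondrially encoded genes, 2 were at least 2-fold lower and 0 at least 2-fold higher (median -0.78, percentile 0). Together they took 5.46% of the counts in the library labelled WT (5.45 to 5.48) and 2.69% in the other (2.68 to 2.70). ND1, a complex I subunit gene, was 1.99-fold lower and ND4 1.83-fold lower, while ND3 was 1.38-fold and COX3 1.23-fold higher, both with the opposite sign after the length and GC correction. ND4 overlaps ND4L and COX3 overlaps ATP6. COX1 was the most abundant transcript of both libraries, and 1.80-fold lower in the library labelled P2X1-KO. Nuclear oxidative phosphorylation genes had a median of 0.49 (percentile 100), with 8 of 79 at least 2-fold higher and 1 at least 2-fold lower. Atp5k was 3.07-fold higher, Ndufa2, opposite to Tmco6, 3.04-fold higher, Atp5g2 3.04-fold lower and Atp5a1 1.49-fold lower. That median was 0.09 (percentile 90.4) after the length and GC correction.

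Branched-chain amino acid genes stayed inside the central 95% of random lists. Of 25 measured, 3 were at least 2-fold lower and 0 at least 2-fold higher (median -0.34, percentile 8.97). The carrier genes Slc43a1 and Slc7a5 were 11.8-fold (7.07 to 21.4) and 2.60-fold lower (2.34 to 2.91), and Bckdk and Slc43a2 were 1.66-fold and 1.37-fold higher. Citric acid cycle genes had a median of -0.30 (percentile 6.87), with 1 of 20 at least 2-fold lower and 0 at least 2-fold higher. Suclg2 was 2.46-fold and Dlst 1.84-fold lower. Glycolysis genes had a median of 0.37 (percentile 93.7), with 3 of 22 at least 2-fold higher and 3 at least 2-fold lower. The list lay above the central 95% when random lists were matched on length (percentile 98.67) and after the length and GC correction (median 0.49, percentile 99.06). Pfkl was 3.14-fold higher and Hk2 2.27-fold lower.

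Purinergic receptor genes differed in both directions. Of 10 measured, 5 were at least 2-fold higher in the library labelled P2X1-KO and 2 at least 2-fold lower (median 1.11, percentile 99.66). P2rx1 itself, at a mean of 3.40 CPM, is a member of the list and is counted among those higher. P2ry6, a receptor for UDP, was 26.1-fold higher (16.4 to 44.1), and Adora2b, an adenosine receptor gene, had 1 and 30 counts, a ratio of 52.7 (8.75 to 2148). P2rx7 was 2.33-fold lower (1.87 to 2.91) and P2rx3, which overlaps Ssrp1, 18.8-fold lower (7.17 to 70.0). With members kept only at a mean of at least 5 CPM, the median was 0.28 (percentile 79.4), inside the central 95%. For release and breakdown of extracellular ATP the median was -0.30 (percentile 24.0) and the mean 0.02, of opposite sign, with 1 of 13 at least 2-fold higher and 2 at least 2-fold lower. Nt5e, encoding the ectoenzyme CD73, was 10.7-fold higher (5.44 to 23.4), and the vesicular nucleotide carrier gene Slc17a9 was 2.24-fold lower (1.94 to 2.60). Calcium signalling genes had a median of -0.09 (percentile 36.6), with 2 of 30 at least 2-fold higher, Trpm4 and Trpm2, and 3 at least 2-fold lower, among them Atp2a2 at 2.69-fold and Itpr3 at 2.31-fold. The calcium median had the opposite sign after the length and GC correction, at 0.12 (percentile 84.0).

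Inhibitors of cyclin-dependent kinases had a higher median, while replication genes lay within 2-fold. Of 6 inhibitor genes measured, 4 were at least 2-fold higher and 0 at least 2-fold lower (median 1.18, percentile 99.85). Cdkn2c was 18.2-fold higher (14.4 to 23.2) and Cdkn2a 11-fold higher (7.94 to 15.5). Of 28 DNA replication genes, 0 differed by 2-fold (median -0.11, percentile 44.8), with Tyms 1.44-fold higher and Cdt1 1.70-fold lower. Of 24 mitosis genes 0 did so, and their median of 0.36 was at percentile 99.51, or at 97.32, inside the central 95%, among random lists not matched on expression. Nusap1, which overlaps Oip5 on the opposite strand, was 1.99-fold higher (1.78 to 2.21), and Bub1b was 1.23-fold lower. Replication histones, whose transcripts mostly lack a poly(A) tail, had 23 of 56 at least 2-fold higher and 2 at least 2-fold lower (median 0.86, percentile 100). After the length and GC correction that median was 0.31 (percentile 99.1). Hist2h4 was 5.85-fold higher and Hist1h2al, with 0 counts in the library labelled P2X1-KO, at least 7.22-fold lower. GENCODE annotates Hist1h2al as a processed pseudogene. Histone genes have near-identical copies, so both values are uncertain.

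The medians of adhesion, inflammatory and lysosomal genes were higher. Of 19 adhesion and homing genes, 12 were at least 2-fold higher and 1 at least 2-fold lower (median 1.15, percentile 100). Itgb7, an integrin subunit gene, was 8.78-fold higher (7.86 to 9.84), Cd48 3.37-fold higher and Icam1 2.32-fold lower (2.03 to 2.66). Of 20 NF-kB and cytokine genes, 8 were at least 2-fold higher and 1 at least 2-fold lower (median 0.88, percentile 99.97). The macrophage growth factor gene Csf1 was 7.94-fold higher (4.91 to 13.4) and the inflammasome sensor gene Nlrp3 4.96-fold higher (3.84 to 6.48). Of 27 autophagy and lysosome genes, 8 were at least 2-fold higher and 0 at least 2-fold lower (median 0.53, percentile 99.68), including Ctsb at 3.48-fold and Psap at 2.87-fold, while Ulk1 was 1.27-fold and Atg16l1 1.21-fold lower. Atg16l1 had the opposite sign after the length and GC correction. Antioxidant genes had a median of 0.45 (percentile 97.93), with 5 of 20 at least 2-fold higher and 1 at least 2-fold lower. The list lay inside the central 95% when random lists were matched on length (percentile 89.69) and after the length and GC correction (median 0.28, percentile 92.88). Hmox1, encoding heme oxygenase, was 15.0-fold higher (13.1 to 17.3) and Nqo1 4.79-fold lower (1.90 to 15.5).

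Marker genes of other cell types were measured as well, although a gate on Mac1 and KIT would remove cells that lack either of them. The mast cell, basophil and eosinophil list was fixed because the gate could hold KIT-bearing or myeloid cells. Among all these marker genes the fibrillar collagen genes stood higher in the library labelled P2X1-KO. Of 6 stroma and endothelium genes measured, 4 were at least 2-fold higher and 0 at least 2-fold lower (median 4.48, percentile 100), led by the collagen genes, and the median was 5.01 with counts of 0 placed at their bound. Pdgfrb was 1.98-fold lower in the library labelled P2X1-KO. Of 17 megakaryocyte and platelet genes 5 were measured, of which 3 were at least 2-fold higher and 0 at least 2-fold lower (median 1.61, percentile 99.3), with Vwf 8.44-fold higher (5.70 to 12.9) and Thbs1 3.11-fold higher. Among platelet transcripts outside the naming rule, named after their values were seen, Pf4 and Ppbp had 0 counts in both libraries, as did Treml1, while Gp1bb had 1 and 6 counts, Gp9 6 and 7 and Tubb1 4 and 0. Mast cell, basophil and eosinophil genes had a median of 0.73 (percentile 97.35), with 3 of 7 at least 2-fold higher and 0 at least 2-fold lower. After the length and GC correction that median was 0.22 (percentile 81.49), while without the 20 most abundant genes in the totals it was 0.54 (percentile 98.16), outside the central 95%. Mcpt8, a basophil protease gene, was 1.48-fold lower. B cell genes had a median of 1.16 (percentile 97.47), with 3 of 5 at least 2-fold higher, such as Cd79b at 3.23-fold, and 0 at least 2-fold lower. This median ranged from 0.47 to 1.66 over the alternatives and its percentile from 88.94 to 98.57. MHC class II and dendritic cell genes had a median of 0.31 (percentile 71.3), with 2 of 5 at least 2-fold higher and 1 at least 2-fold lower. Over the alternatives their median ranged from 0.16 to 1.47 and its percentile from 63.0 to 97.1. Cd74 was 4.53-fold higher and H2-Ab1, with 44 and 3 counts, had a ratio of 8.36 in the other direction (2.68 to 42.1). For T and NK cells 2 genes were measured, Lck with 32 counts in the library labelled WT and 2 in the other, and Bcl11b with 94 and 95. For erythroid cells 1 gene, Rhd, was measured, with 16 and 17 counts. These T and NK cell and erythroid counts are not scaled for depth. Level counts mean a higher CPM in the library labelled P2X1-KO, which has the smaller total.

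The stress, signalling and sex-linked lists that remain lay inside the central 95%. Interferon response genes had a median of -0.16 (percentile 34.9), with 4 of 22 at least 2-fold higher and 5 at least 2-fold lower. Ifit2 was 10.9-fold lower (5.15 to 27.6), Oas2 6.70-fold lower (5.12 to 8.92) and Mx2, with 0 counts in the library labelled WT, at least 10.5-fold higher against the floor (lower bound of the exact interval 7.72). Apoptosis genes had a median of 0.01 (percentile 70.6), with 2 of 23 at least 2-fold higher and 1 at least 2-fold lower, which was Bok at 95 and 0 counts, at least 18-fold lower. For p53 targets the median was -0.18 (percentile 34.2), with 1 of 21 at least 2-fold higher, Cdkn1a at 2.13-fold, and 3 at least 2-fold lower, among them Zmat3 at 3.51-fold. For the ATF4 and amino acid response it was 0.07 (percentile 71.8), with 4 of 21 at least 2-fold higher and 3 at least 2-fold lower. Nupr1 was 29.5-fold higher (13.1 to 82.4) and Slc7a1 3.27-fold lower (2.89 to 3.72). Unfolded protein response genes had a median of 0.14 (percentile 75.5), with 0 of 19 at 2-fold in either direction. With total counts as the scale, the medians of the apoptosis, ATF4 and unfolded protein lists had the opposite sign. The hypoxia list had a median of 0.32 (percentile 96.4), with 3 of 13 at least 2-fold higher, such as Ankrd37, and 1 at least 2-fold lower, which was Egln3. Among genes sensitive to handling, immediate early genes had a median of 0.43 (percentile 87.2), with 2 of 19 at least 2-fold higher and 1 at least 2-fold lower. Nr4a1 was 3.16-fold higher and Fosb 2.14-fold lower. Heat shock genes had a median of 0.23 (percentile 75.7), with 1 of 11 at least 2-fold higher, Serpinh1 at 1 and 19 counts, and 1 at least 2-fold lower, Hspd1. Of 3 sex-linked genes measured (median 0.56, percentile 64.4), Xist had 13620 counts in the library labelled WT and 3526 in the other, Ddx3y 32 and 29, and Eif2s3y 40 and 50. Xist and the Y-linked genes mark different sexes, so the median over them cannot show a difference in the mix of sexes. Scaled for depth, Xist was 2.20-fold lower in the library labelled P2X1-KO (2.12 to 2.28). Ddx3y was 1.59-fold higher there (0.93 to 2.71) and Eif2s3y 2.19-fold higher (1.42 to 3.41).

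In total 16 of 38 lists lay above the central 95% of random lists, 4 below and 18 inside. For lists of unrelated genes, 1.9 would be expected outside. Random lists hold unrelated genes, whereas members of a fixed list may vary together. The excess over 1.9 is therefore no measure of a departure from chance. Values of Bcl2, Msi2, Dkc1, Atp5a1, Trpm4, Hspd1, Ankrd37, Ddx3y and Xist are uncertain because each overlaps another counted gene. Short transcripts stood higher in the library labelled P2X1-KO over all genes. Spearman's rho of the log2 difference with exon length was -0.31 across 10226 genes, which are not independent replicates, and with GC content 0.16. When the genes were ordered by exon length into 10 equal parts, the shortest part (64 to 1467 bases) had a median of 0.61 and the longest (9754 to 123179 bases) -0.43. Processed pseudogenes (343 genes) had a median of 0.69 and protein-coding genes (9604) -0.11. After correction for length and GC, the list medians were 0.52 for ribosomal proteins, 0.31 for histones, 0.71 for primary granules, 1.57 for late neutrophil genes and 2.21 for monocyte genes, all above the central 95%. The HOXA list had a corrected median of -0.34 (percentile 1.83), MYC and ribosome biogenesis -0.66 and cholesterol synthesis -0.69.

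**Figure D3:**
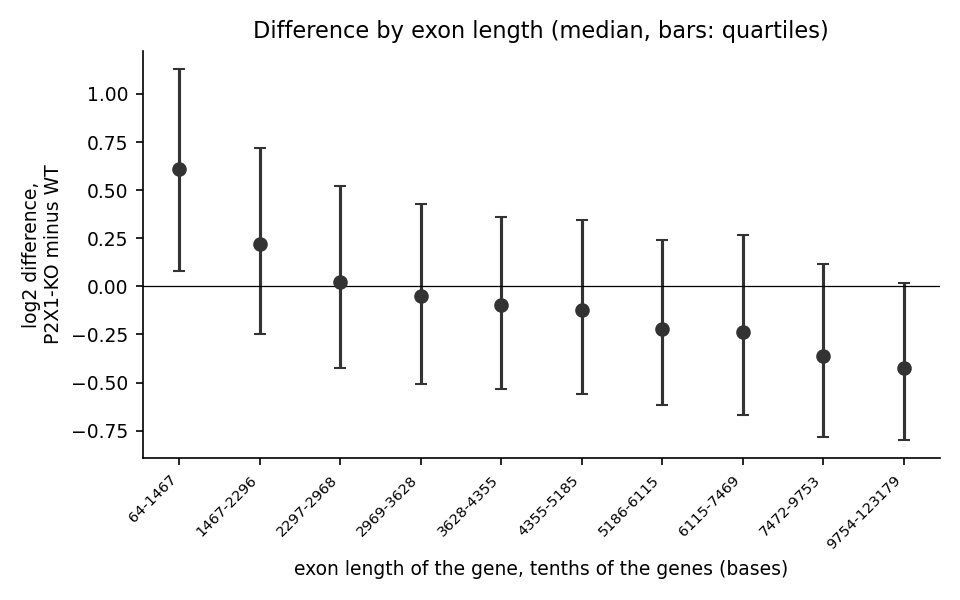
Log2 difference (y axis, P2X1-KO minus WT, CPM + 0.5) by exon length in bases (x axis, 10 equal parts of the 10226 genes with a known length and a mean of at least 5 CPM), 1 library per group. Points are medians and bars run from the lower to the upper quartile of genes; the median passes from 0.61 in the shortest part to -0.43 in the longest.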

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

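Of the alternatives, only the length and GC correction and TMM without mitochondrial and rRNA genes were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers and there was 1 library per group. P2rx1 stayed higher in the library labelled P2X1-KO under all 8 alternatives that rescaled or corrected it, with log2 differences from 0.92 to 1.5. Medians of the late neutrophil list ranged from 1.57 to 2.24, of the monocyte list from 2.02 to 2.44, of the HOXA list from -0.79 to -0.34, of MYC and ribosome biogenesis from -0.94 to -0.66 and of cholesterol synthesis from -0.97 to -0.64 over 11 alternatives, each on the same side of the central 95%. The branched-chain list stayed inside it. Over genes with a mean of at least 5 CPM, the median was -0.08 with TMM and -0.26 with total counts. It was -0.28 with total counts without the 20 most abundant genes. List medians are best read relative to such values, although lists used genes of at least 1 CPM, whose TMM median was -0.06. Total counts without the 20 most abundant genes gave 1668 genes at least 2-fold lower, against 1053, because every gene is shifted by the same factor. Without the expression filter 2494 genes were at least 2-fold higher and 2547 lower, and at a mean of at least 20 CPM 720 and 593, since more or fewer genes enter. At 1.5-fold 2257 were higher and 2495 lower, and at 4-fold 440 and 202, as the thresholds imply; at 4-fold 68.5% of these were higher. All other counts stayed within 1.5 times those reported, including 1242 and 1066 with the WT library thinned.

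Of 32 other lists, 7 crossed the bound of the central 95% under some alternative. The antioxidant, mitosis, nuclear oxidative phosphorylation and purinergic lists came to lie inside it, and the glycolysis, B cell and mast cell, basophil and eosinophil lists outside it. The median of nuclear oxidative phosphorylation was 0.09 (percentile 90.4) after the length and GC correction, and the purinergic median 0.28 (percentile 79.4) at a mean of at least 5 CPM. The cause was not tested. Of 170 genes taken by the naming rule besides P2rx1, 0 of those at 2-fold or more changed sign and 6 of those under 2-fold did, namely ND3, COX3, Sod2 and Atg16l1 after the length and GC correction and Cd79a and Csf2rb2 with upper-quartile scaling. Depth limits genes such as Bcat1, whose 26 and 0 counts allow no upper limit on the fold.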

Other observations

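All tests below except that of sequencing depth were chosen after the result was seen. Genes in this part that the naming rule does not hold were chosen after their values were seen. As in the report, directions rest on labels that P2rx1 goes against. Mycn, a MYC family transcription factor gene, was 20.3-fold lower in the library labelled P2X1-KO (18 to 23.1), at 602 CPM against 29.6 CPM, while Myc was 6.08-fold higher. Rbp4, encoding the retinol-binding protein that STRA6 receives, was 38.7-fold lower (18.6 to 96.7), alongside Stra6. Hoxa9 and Hoxa10 were nearly level, at 301 and 261 CPM and at 75.2 and 75.7 CPM. Among Pbx3, Hoxa9 and Hoxa10, the nearest bounds of the largest and smallest fold lay 9.33-fold apart.

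Ear2, an eosinophil-associated ribonuclease gene, was 87.4-fold higher (37.0 to 272), in the same direction as Prg2, whereas Epx, encoding eosinophil peroxidase, had 1 and 5 counts. Gata2, a transcription factor gene of progenitors and mast cells, was 4.81-fold higher (4.11 to 5.65). S100a8, encoding a neutrophil calcium-binding protein, was 10.1-fold higher (9.78 to 10.4), and Elane, encoding neutrophil elastase, 1.80-fold higher (1.77 to 1.83). Both libraries held Xist, a transcript of female cells, together with the Y-linked transcripts Ddx3y and Eif2s3y. Xist was 2.20-fold lower in the library labelled P2X1-KO, Eif2s3y 2.19-fold higher and Ddx3y 1.59-fold higher (0.93 to 2.71). A different mix of female and male cells in the libraries was not tested, and it may bear on other differences. After the length and GC correction, the chromosome median farthest from that of all genes with a mean of at least 5 CPM was 0.141 above it, on chromosome 1.

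The medians of the late neutrophil and monocyte lists were 2.13 and 2.22. After the length and GC correction the smaller of them was 1.57, so the tables argue against that trend as the whole cause. With the WT library thinned to the depth of the other, the smaller median was 1.94. Thinning leaves the expected ratio of scaled counts unchanged, so this value cannot decide whether depth played a part. Mature neutrophils remain open, although they lack KIT and the gate would remove them. Their terminal transcripts (12 measured, 6 of them also in the late neutrophil list) had a median of 0.77 with an SD of 1.47, below the list but within that spread. The SD runs over genes and is not an error of the median, so this does not decide the question. G0s2, Slfn4, Mxd1, Ly6g and Il1r2 were lower (log2 differences -2.15 to -0.25). Csf3r, Ccl3, Msrb1, Cxcr2, Il1b, Retnlg and Clec4d were higher (0.72 to 2.26). A shift in differentiation tied to the genotype was not tested, because genotype and library cannot be separated with 1 library each.

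For P2rx1, which was not lower under the P2X1-KO label, counting error is argued against by the lower bound of the fold, 1.78. Platelet RNA is argued against by the 0 summed counts of Pf4 and Ppbp, the abundant platelet transcripts, beside 45 of P2rx1 in that library. An exchange of the labels cannot be told apart from a transcript that persists without a working protein, because the fold of 2.93 comes from the only genotype marker the table holds. Other causes, such as an ineffective knockdown, which the protocol wording leaves possible, were not tested.

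For the collagen genes, the length and GC trend is argued against by a smallest corrected log2 difference of 5.96 among Col1a1, Col1a2 and Col3a1. Fibroblasts or osteoblasts in the sort, which a Mac1 and KIT gate would remove, may be a source. Of 17 abundant transcripts of these cells, 9 had more than 3 counts in the library labelled P2X1-KO. The median over all 17 was 0.301% of the 1327 counts of Col1a1. Sparc had 0 counts in the library labelled WT and 36 in the other and Bgn 1 and 40, and Col5a2, Serpinh1 and Mmp2 were also higher. Fbn1 had 28 and 20, a scaled log2 difference of 0.26. Dcn, Lum, Ibsp, Igfbp5 and Col6a2 had 0 in both. Col6a3, at 429 and 8, Cxcl12, at 14 and 0, and Bglap, at 9 and 0, went the other way. No measured profile of such cells was at hand to say what share they would bring, so this stays open, and no biological explanation of the collagen genes was tested.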
